A study of Mus musculus with 5 samples.

How the data were processed

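Total RNA of 3 mouse gliomas and 2 normal brain samples, all from postnatal day 150 per the labels, was measured on single-colour Agilent SurePrint G3 mouse 8x60K arrays, 1 array per sample. The scanner files hold intensity values of each spot, which the authors produced with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, that step subtracts background with spatial detrending, and no scaling between arrays is recorded. The same deposited files hold 0 or 1 flags of each spot, set by the authors' Feature Extraction run per the file headers. The authors' value table holds log2 values as deposited, and these were checked to equal the log2 of the processed signal, with a median difference of 0 and a correlation of 1 on every array.

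Signal over background stands for depth here. Well above background were 65.92%, 70.3%, 68.47%, 63.96% and 61.45% of the spots other than controls on glioma arrays 1 to 3 and normal brain arrays 1 and 2, and the 75th percentile of the signal was 906.9, 1055, 865.6, 723.3 and 743.3. No spot other than controls was saturated. All arrays lay on 1 slide with 1 scan, the gliomas in its first row and the normal brain samples in its second, so slide row and group are the same split. In 273 probes printed at least 5 times, log2 differences between the normal brain arrays had an SD of 0.165 against an expected spot error of 0.026, and those between glioma arrays an SD of 0.554 to 0.631. These checks do not settle whether the RNAs of a group came from separate animals, except that glioma 3 differs in sex from gliomas 1 and 2.

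Control spots were left out, repeated spots of a probe were averaged, and 23 probes with outlier flags on all their spots of an array were left out. The log2 processed signal minus the array's 75th percentile was used. Of 55681 probes, 29796 carry a RefSeq accession and 28026 of these were named through the supplied list of RefSeq accessions. The 16194 probes for genomic intervals and the 9691 others received no gene name. Each of the 21154 named genes was represented by its brightest probe over all 5 arrays, and 16891 whose probe was well above background on at least 2 arrays were tested. Of the called genes with several detected probes, 252 of 2426 had a probe in the opposite direction.

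Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05), with version 1.17.8 of the data.table package, Python 3.11.15 and matplotlib 3.10.9 for tables and figures. A total of 36 gene lists, written before the values were seen, were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation was given beside it, since the preset value treats genes as nearly independent. Fry, which tests whether a list moves on balance in a single direction and does not compare it with other genes, was a further alternative. Of 556 list members, 528 were measured, 15 were named on the array and not detected, and 13 names were not matched, several of them synonyms of matched members. Where a gene was not well above background on any array of 1 group and well above it on every array of the other, a lower bound of its fold was computed with each array of that group set to its lowest value well above background, or to the gene's own value where higher. These bounds are approximate. They hold for the processed signal, and background correction with an offset gives smaller changes for dim probes. The lowest value, called the floor here, is taken over all probes of an array, and some probes above it were not well above background. On normal brain array 1 the floor was -6.15, and Igf2bp2 was not well above background at -5.01. Genes detected on only some arrays of a group are given as fitted changes with the number of arrays that detected them. With the 23 list members that had a lower bound set to it, the medians of all 36 lists stayed within 0.01. Few members had a bound and partly detected genes were given none, so this says little about the effect of dim genes.

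Genes were named by a rule fixed beforehand. It took the 10 largest rises and falls among called genes detected on all arrays without overlap of the groups, leaving out clone names, and the 5 largest lower bounds in each direction. It also took up to 3 called members of each list in its main direction and 2 in the other, the driver genes, and the sex-linked Xist, Ddx3y, Eif2s3y and Kdm5d. Gfap, the chromosome 7 genes other than Haus5 and Atp4a, and the genes of the other observations were chosen after their values were seen. A few genes that the rule names are not reported.

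The fit was tested on simulated data with 16891 genes in 10 runs. It recovered 8.2% of 2-fold and 50.4% of 4-fold changes among 100 changed genes of each size, with 4.25% of calls among unchanged genes and none of the wrong sign. Few genes were changed in a run, whereas 8687 of 16891 were called in the data. The adjustment was therefore stricter in the simulation, and these shares do not give the recovery in the real comparison. A shifted list of 20 genes passed camera in 10 runs and an unchanged list in 0. The simulated genes varied independently, so this does not test the inter-gene correlation on which the real lists depend. When all genes changed as fitted, 99.7% of calls had the right sign. The planted changes were the fitted ones, which include the noise of these arrays. This share therefore does not give the accuracy of signs in the data. A planted block of neighbouring genes was found in 10 of 10 runs and shuffled neighbours in 0. That scan used independent random numbers unrelated to the arrays and a strongly raised block. It checks only that the scan runs as meant, not its behaviour with co-regulated neighbours.

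Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' value table, 2 other detection filters, the mean of all detected probes, eBayes with trend and robust, array weights, the replicate number as a block, each sample left out and limma treat at 1.5-fold. Normexp used the median spot signal, as a mean signal column was not used here. Gene order was taken from the supplied table for GRCm38, whereas the interval probes carry mm9 coordinates, so the interval probes were not placed among the genes.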

Results

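Total RNA from mouse glioma and from normal mouse brain, all collected at postnatal day 150, was hybridised to single-colour Agilent 60K mouse expression arrays. The gliomas came from a model built on mosaic analysis with double markers, in which recombination during cell division leaves sparse, colour-marked mutant cells. Glioma was represented by 3 arrays and normal brain by 2. Each array carried 59305 spots for 55681 probes other than controls. The share of spots well above background was 65.9%, 70.3% and 68.5% on glioma arrays 1 to 3, and 64.0% and 61.5% on normal brain arrays 1 and 2. The number of arrays limits the precision of every value below. The labels number the replicates without saying whether they came from separate animals, so the p-values measure the spread between these samples. Among the gliomas this spread is not only technical, as glioma 3 differed in sex from gliomas 1 and 2. Gliomas 1 and 2 also differed in runs of neighbouring genes described below, though whether they came from separate animals is not settled. Between the normal brain samples the spread may be technical. Fold changes are glioma over normal brain, ± the standard error of the limma fit, with n = 3 and n = 2.

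Sex-linked transcripts differed within the glioma group. Xist, the RNA that silences the second X chromosome of females, was well above background on glioma array 3 only, at a log2 level of 0.01 relative to the array's 75th percentile, against -7.61 and -7.45 on glioma arrays 1 and 2 and -7.16 and -7.03 on the normal brain arrays. The Y-linked Ddx3y and Eif2s3y were well above background on the other 4 arrays and not on glioma array 3, and the probe for Kdm5d was not well above background on any array. Glioma 3 thus carried the transcripts of a female, and gliomas 1 and 2 and both normal brain samples those of males.

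The comparison of glioma with normal brain asks which transcripts distinguish the tumour samples from the normal brain samples. Across the probes detected on all 5 arrays, the gliomas correlated with each other at r = 0.976 to 0.985, the normal brain samples at r = 0.996, and samples of different groups at r = 0.896 to 0.912. These correlations are across probes, which are not independent replicates. Among 16891 genes tested, 8687 differed at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Of these, 3994 were higher and 4693 lower in glioma, so that 46.0% of the calls were higher. In the authors' value table, which is not scaled between arrays, the corresponding numbers were 5598 higher and 3185 lower, or 63.7% higher, because the median log2 change of all genes was 0.31 there against -0.05 in the scaled values. A change of at least 2-fold was found in 2626 of the higher and 3391 of the lower genes. In 12509 genes, 74.1% of those tested, the glioma and normal brain values did not overlap, where chance gives 20% for 3 arrays against 2. Of the called genes, 419 were well above background on all glioma arrays and on no normal brain array, and 204 the other way round. The number of calls rested on both normal brain samples, falling to 4630 without replicate 1 and to 4649 without replicate 2.

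Trp53 and Nf1, the tumour suppressors inactivated in published gliomas of this kind, were examined first. Trp53 was 1.84-fold higher in glioma (log2 change 0.88 ± 0.16, adjusted p = 0.00774) and Nf1 1.41-fold lower (-0.50 ± 0.13, adjusted p = 0.0289). The labels used here name no mutated gene, and which exons the probes match is not known, so these values do not check a deletion. In the authors' unscaled value table Nf1 changed by only -0.14 and did not pass. Cdkn2a, whose locus encodes the cell cycle inhibitor p16 and the p53 activator p19Arf, showed the largest rise of any gene detected on all arrays, 447-fold (log2 change 8.80 ± 0.27, adjusted p = 0.000328), or 181-fold with normexp background correction, whose offset shrinks changes of dim probes. The growth-promoting transcription factor Myc rose by 4.25 ± 0.19 on the log2 scale, cyclin D genes Ccnd1 and Ccnd2 by 3.32 ± 0.33 and 3.26 ± 0.25, and their kinase partner Cdk4 by 2.76 ± 0.16. Cdk6 passed the test as higher, but its probe was well above background on only 2 of the 3 glioma arrays and on neither normal brain array, so no size is given. Rb1, Mycn and Idh1 rose by 1.31, 0.95 and 0.50. The growth factor genes Pdgfa and Pdgfb fell by 1.33 ± 0.13 and 1.86 ± 0.31, and the receptor gene Egfr fell by 1.01 ± 0.18. Atrx, Tert and Mdm4 did not pass, with log2 changes of 0.25, 0.21 and -0.52. In all, 10 of the 18 driver genes measured rose and 5 fell, and the list as a whole did not pass camera's test (adjusted p = 0.0619). That result depends on single arrays: the list passed without glioma replicate 2 (adjusted p = 0.0384) and without normal brain replicate 1 (0.0474) or 2 (0.0375).

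**Figure D1:**
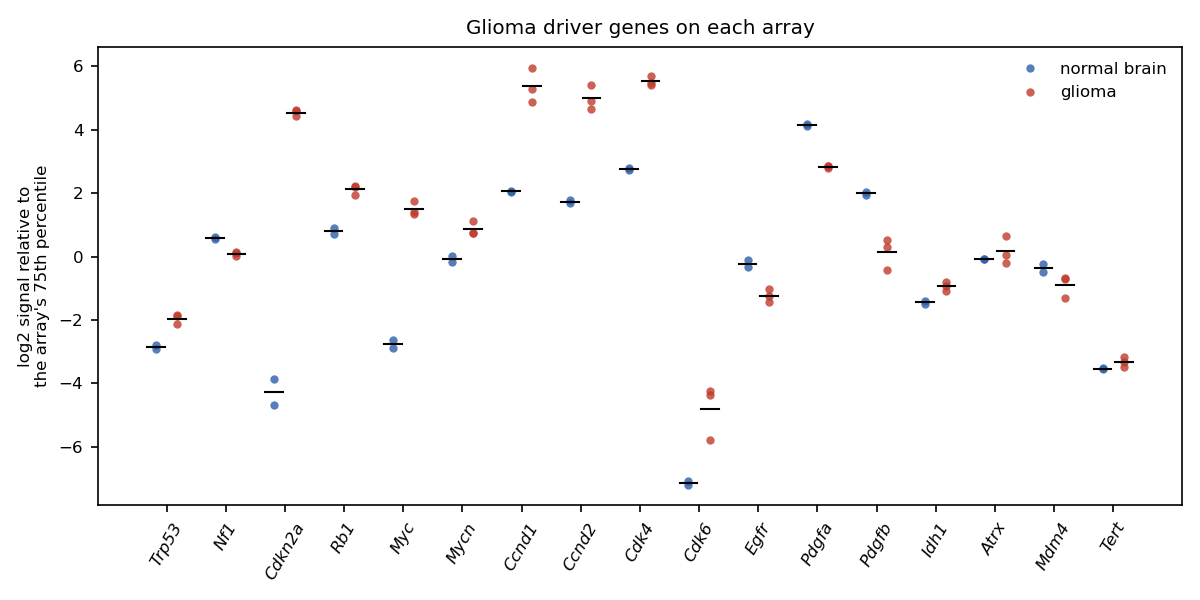
Log2 signal relative to the array's 75th percentile (vertical axis) of glioma driver genes, with 1 point per array, normal brain in blue (n = 2) and glioma in red (n = 3), and a bar at each group mean. Cdkn2a and Myc lie 8.80 and 4.25 log2 units higher in glioma, and Pdgfb 1.86 units lower.

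Genes of cell division rose together. All 23 measured members of the G2 and mitosis list were higher in glioma, with a median log2 change of 4.77 (camera adjusted p = 6.54e-12, adjusted p = 0.317 with an estimated correlation). Cyclin B1 (Ccnb1) rose by 7.60 ± 0.33, with its probe well above background on 1 of the 2 normal brain arrays. The mitotic kinase genes Cdk1 and Bub1, not well above background in normal brain, were at least 33.6-fold and at least 34.9-fold higher. Such values are approximate lower bounds, taken against each array's lowest value well above background, or the gene's own value where higher. Of 23 DNA replication genes, 22 rose, with a median of 3.12 (adjusted p = 1.9e-11, adjusted p = 0.317 with an estimated correlation). Among them were the thymidine kinase Tk1 (6.15 ± 0.30), Uhrf1, which guides maintenance of DNA methylation (5.46 ± 0.27), and the chromatin assembly gene Chaf1b (5.13 ± 0.18).

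Lineage markers moved in different directions. Of 19 oligodendrocyte progenitor genes, 16 rose and none fell, with a median of 2.82 (adjusted p = 6.15e-08, adjusted p = 0.239 with an estimated correlation). The proteoglycan NG2 gene Cspg4 rose by 4.74 ± 0.17, the growth factor receptor gene Pdgfra by 4.56 ± 0.40 and the lineage factor Olig2 by 4.49 ± 0.17. Neural stem and progenitor genes rose in 14 of 18 cases and fell in 1, or 15 and 1 when adjusted over the list alone, with a median of 2.50 (adjusted p = 9.18e-06, adjusted p = 0.239 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, rose by 5.09 ± 0.14 and the Notch ligand gene Dll3 by 4.39 ± 0.21, while Msi1 fell by 1.17 ± 0.16 on its brightest probe and changed by 0.11 when its detected probes were averaged. Of 18 genes of mature oligodendrocytes and myelin, 10 fell and none rose, with a median of -1.56 (adjusted p = 0.00943, adjusted p = 0.467 with an estimated correlation). Opalin, detected on 2 of 3 glioma arrays, fell by 4.96 ± 0.54, Aspa by 3.29 ± 0.65 and Mobp by 3.15 ± 0.48. Of 17 astrocyte genes, 9 fell and none rose, with a median of -0.88 (adjusted p = 0.0207, adjusted p = 0.467 with an estimated correlation). The connexin genes Gja1 and Gjb6 fell by 3.15 ± 0.58 and 3.1 ± 0.45 and Agt by 2.43 ± 0.61, whereas Gfap, the astrocyte filament gene, did not pass (0.34 ± 0.43).

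Neuronal transcripts were lower throughout the lists examined. All 17 pan-neuronal genes fell, with a median of -3.29 (adjusted p = 1.6e-07, adjusted p = 0.33 with an estimated correlation), led by the neurofilament genes Nefm, Nefl and Nefh, which fell by 4.73, 4.67 and 4.49. Of 15 glutamatergic genes 12 fell, with a median of -2.85 (adjusted p = 2.26e-05, adjusted p = 0.33 with an estimated correlation), including Neurod6 (-4.05 ± 0.84) and the NMDA receptor subunit genes Grin2a (-3.92 ± 0.16) and Grin2b (-3.48 ± 0.16). Of 14 GABAergic genes 13 fell, or 14 when adjusted over the list alone, with a median of -3.30 (adjusted p = 5.79e-06, adjusted p = 0.317 with an estimated correlation). The calcium-binding protein genes Calb2 (detected on 2 of 3 glioma arrays) and Pvalb fell by 5.56 ± 0.41 and 4.88 ± 0.33.

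Markers of brain regions and of tissues lining the ventricles differed between the groups. The labels do not say which part of the brain the normal samples or the tumours came from. All 12 choroid plexus genes fell, with a median of -5.38 (adjusted p = 1.06e-06, adjusted p = 0.244 with an estimated correlation): Ttr, which encodes transthyretin, fell by 13.12 ± 0.27 with its probe well above background on 2 of 3 glioma arrays, Kcne2 by 7.71 ± 0.95 with its probe well above background on 1 of 3, and Folr1 by 7.60 ± 0.56. Of 11 ependymal genes 10 fell, with a median of -2.48 (adjusted p = 0.00228, adjusted p = 0.33 with an estimated correlation), including Tmem212 (-6.38 ± 1.40, well above background on 1 of 3 glioma arrays), Ccdc153 (-4.83 ± 0.77) and Spag6l (-3.73 ± 0.37). All 11 striatal genes fell, with a median of -2.28 (adjusted p = 6.99e-06, adjusted p = 0.239 with an estimated correlation), including the dopamine receptor gene Drd1 and the adenosine receptor gene Adora2a at -2.95 and -2.76. Of 12 genes of cortex and hippocampus 7 fell, or 8 when adjusted over the list alone, with a median of -1.91 (adjusted p = 0.000344, adjusted p = 0.239 with an estimated correlation), led by Lamp5, Emx1 and Fezf2 at -4.21, -3.47 and -3.43. Among 13 genes of diencephalon, midbrain and hindbrain 9 fell and 2 rose, with a median of -3.12 (adjusted p = 0.0467, adjusted p = 0.317 with an estimated correlation). This call was lost without any 1 of the gliomas (adjusted p = 0.0532, 0.0515 and 0.0843 without replicates 1, 2 and 3). The hypothalamic hormone genes Avp and Oxt fell 277-fold and 182-fold, and Slc17a6, a vesicular glutamate transporter, 62.8-fold. The homeobox gene Hoxa5 and Tph2, the neuronal enzyme of serotonin synthesis, were at least 25.7-fold and at least 11.8-fold higher in glioma. With normexp their fitted log2 changes were 3.15 and 1.88, smaller than these bounds. The cerebellar list (adjusted p = 0.14) and the olfactory bulb list (adjusted p = 0.36) did not pass. Of 10 cerebellar genes, 2 rose and 4 fell, or 6 fell when adjusted over the list alone: En2 and Car8 rose by 2.92 and 1.01, Neurod1 and Ppp1r17 were at least 16-fold and at least 3.9-fold lower, and Cbln1 fell by 2.54. The cerebellar list did pass without glioma replicate 2 (adjusted p = 0.0489). Of 10 olfactory bulb genes, 2 rose and 4 fell, or 5 fell when adjusted over the list alone: Shisa3 and Tbx21 were at least 9.88-fold and at least 1.59-fold higher, and Sp8 (detected on 2 of 3 glioma arrays), Cdhr1 and Th fell by 3.61, 3.03 and 1.94.

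**Figure D2:**
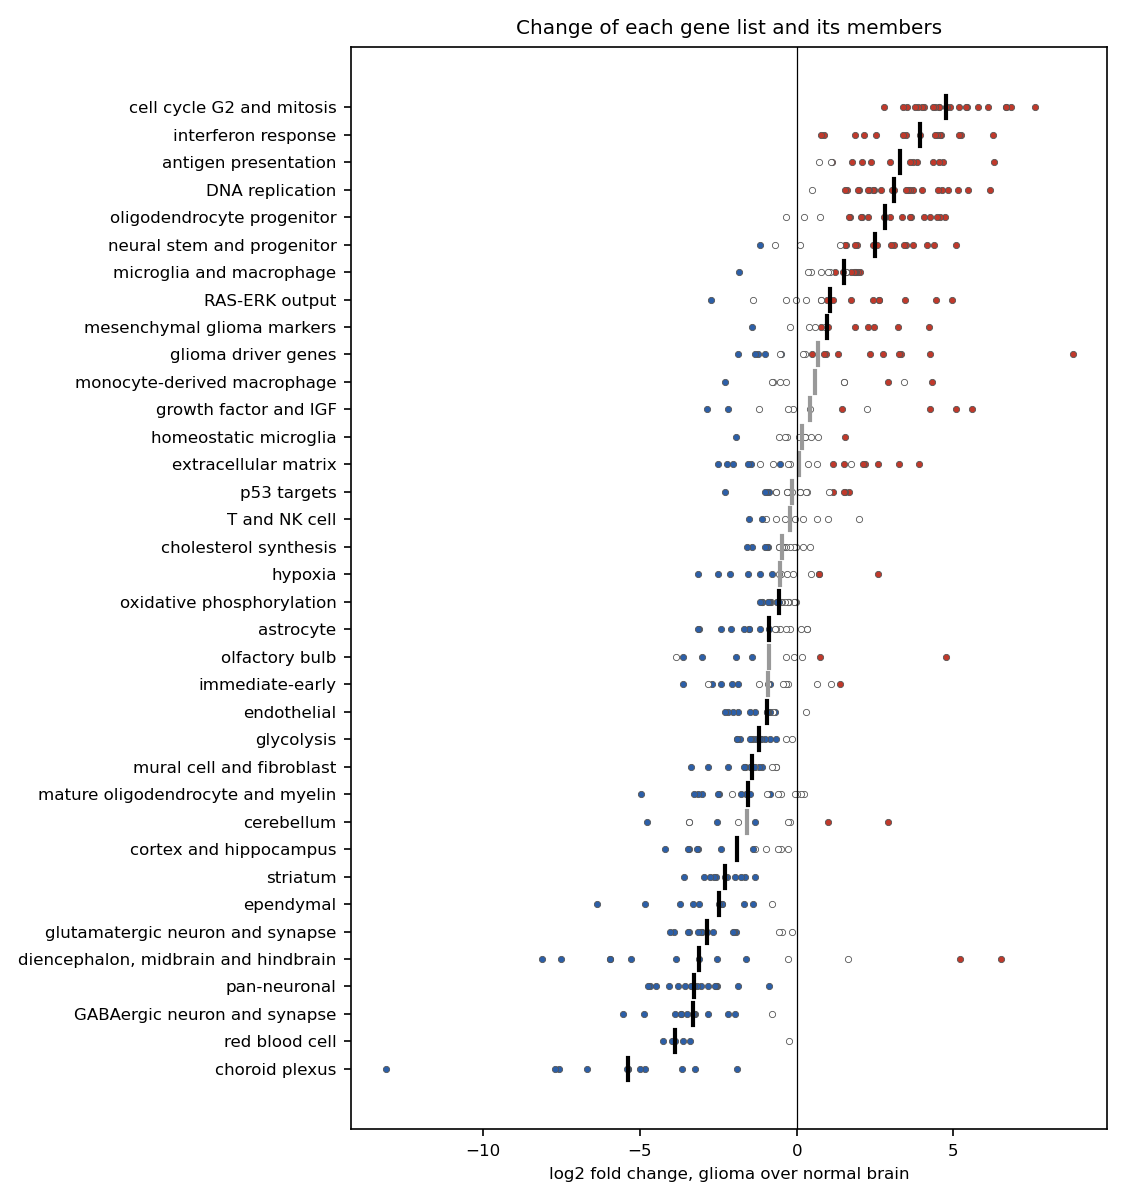
Log2 fold change of glioma over normal brain (horizontal axis) for the measured members of 36 gene lists (vertical axis), with 1 point per gene, filled where the adjusted p was under 0.05 (red higher, blue lower), and a bar at each list's median, black where camera's adjusted p was under 0.05 and grey otherwise. The medians run from 4.77 for G2 and mitosis to -5.38 for choroid plexus.

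Antigen presentation and interferon genes rose. Of 14 antigen presentation genes 12 rose, or 13 when adjusted over the list alone, with a median of 3.30 (adjusted p = 1.06e-06, adjusted p = 0.239 with an estimated correlation). Nlrc5, the activator of class I genes, rose by 6.28 ± 0.39 with its probe detected on 1 of 2 normal brain arrays, the immunoproteasome gene Psmb8 by 4.67 ± 0.25 and the class I gene H2-K1 by 4.55 ± 0.18, for which near-identical class I copies may share the probe's signal. All 15 interferon response genes rose, with a median of 3.94 (adjusted p = 1.43e-06, adjusted p = 0.33 with an estimated correlation), including the chemokine Cxcl10 (6.27 ± 1.00, detected on 1 of 2 normal brain arrays), Usp18 (5.24 ± 0.42) and Oas1a (5.16 ± 0.64). Another chemokine gene, Ccl5, rose 165-fold. Of 16 microglia and macrophage genes 9 rose and 1 fell, or 10 and 1 when adjusted over the list alone, with a median of 1.52 (adjusted p = 0.00482, adjusted p = 0.541 with an estimated correlation), and fry did not call this list (adjusted p = 0.105). The complement genes C1qa and C1qc rose by 2.02 ± 0.36 and 1.90 ± 0.42 and the receptor subunit gene Fcer1g by 1.96 ± 0.34, while the integrin gene Itgam fell by 1.83 ± 0.56, with another of its detected probes going the opposite way. Tyrobp, a member of this list, lies in the chromosome 7 stretch described with Haus5. The myelin list also has a member there, Mag. The lists for homeostatic microglia (adjusted p = 0.712), monocyte-derived macrophages (adjusted p = 0.439) and T and NK cells (adjusted p = 0.738) did not pass, with medians of 0.16, 0.58 and -0.22. Their called members were Sall1 (1.55) and Olfml3 (-1.95, with a detected probe in the opposite direction) in the first of them. In the macrophage list Lyz2 rose by 2.90 and S100a4 by 1.51, Plac8 was at least 14.5-fold higher and F13a1 fell by 2.29. In the T and NK list Zap70 and Cd4 fell by 1.52 and 1.12.

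Vessel and blood genes fell. Of 14 endothelial genes 12 fell, with a median of -0.94 (adjusted p = 0.000353, adjusted p = 0.317 with an estimated correlation), including the receptor genes Flt1 (-2.29 ± 0.19) and Tek (-2.03 ± 0.17) and the transporter gene Slco1c1 (-2.20 ± 0.15). Of 14 mural cell and fibroblast genes 11 fell, with a median of -1.42 (adjusted p = 0.000203, adjusted p = 0.317 with an estimated correlation), including Lum, Dcn and Vtn at -3.39, -2.82 and -2.20. Of 7 red blood cell genes 6 fell, with a median of -3.89 (adjusted p = 0.000203, adjusted p = 0.317 with an estimated correlation). The haemoglobin genes Hbb-bt, Hbb-b2 and Hbb-b1, whose near-identical sequences may share signal, fell by 4.26, 3.97 and 3.94.

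Signalling and matrix lists were mixed. Of 16 RAS-ERK output genes 10 rose and 1 fell, with a median of 1.07 (adjusted p = 0.00286, adjusted p = 0.33 with an estimated correlation). The feedback inhibitor gene Spry1 rose by 4.97 ± 0.26 and the ETS factor Etv4 by 4.46 ± 0.30, Spry4 was at least 3.1-fold higher, and the phosphatase gene Dusp5 was at least 4.55-fold lower. Of 12 mesenchymal glioma markers 7 rose and 1 fell, with a median of 0.95 (adjusted p = 0.00587, adjusted p = 0.317 with an estimated correlation): Runx1 (detected on 1 of 2 normal brain arrays), Tnfrsf1a and Lgals3 rose by 4.21, 3.24 and 2.48 and Anxa1 fell by 1.43. The extracellular matrix list did not pass (adjusted p = 0.694, median 0.06), with 7 genes higher and 6 lower of 20, or 8 and 7 when adjusted over the list alone. Lama4 and Mmp2 rose by 3.92 and 3.28 and Lox was at least 2.34-fold higher, while Col6a1 fell by 2.24 and Mmp9 was at least 2.01-fold lower. The p53 target list did not pass (adjusted p = 0.961), with 4 genes higher and 4 lower of 19, and its median (-0.17) and mean (0.01) differed in sign. Trp53inp1, Bbc3 and Pmaip1 rose by 1.67, 1.56 and 1.51, and Perp and Ccng1 fell by 2.30 and 1.00. The IGF list did not pass (adjusted p = 0.31), with 4 genes higher and 2 lower of 11. The RNA-binding protein genes Igf2bp3 and Igf2bp2 were at least 16.8-fold and at least 29.7-fold higher, Igfbp3 rose by 4.26 ± 0.45, and Igf2 and Igfbp5 fell by 2.86 and 2.20. Immediate-early genes did not pass as a list (adjusted p = 0.138), with Jun higher by 1.37 and 6 of 15 genes lower, including Arc, Fosb and Egr4, which fell by 3.64, 2.71 and 2.40. Without glioma replicate 1 that list passed (adjusted p = 0.0236).

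Metabolic lists were lower where they passed. Of 15 glycolysis genes 13 fell, with a median of -1.19 (adjusted p = 9.55e-05, adjusted p = 0.33 with an estimated correlation), including Aldoa, Tpi1 and Pfkp at -1.92, -1.89 and -1.82. Of 19 oxidative phosphorylation genes 9 fell, with a median of -0.57 (adjusted p = 0.00342, adjusted p = 0.462 with an estimated correlation), including Uqcrc2, Ndufv1 and Ndufb8 at -1.18, -1.12 and -1.09. The hypoxia list did not pass (adjusted p = 0.294), with 6 of 14 genes lower, among them Ndrg1, Bnip3 and the vessel growth factor gene Vegfa at -3.15, -2.52 and -2.14, and with Hk2 and Kdm3a higher by 2.58 and 0.71. The cholesterol synthesis list did not pass (adjusted p = 0.0988), with 5 of 16 genes lower, or 3 when adjusted over the list alone, including Msmo1 and Fdft1 at -1.57 and -1.42. It passed without glioma replicate 1 (adjusted p = 0.025).

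The largest single changes were not all in these lists. Among genes detected on all arrays, the largest rises after Cdkn2a and Ccl5 were those of the homeobox gene Gsx1 (138-fold), the lipase gene Pnlip (118-fold), Hoxa7 (114-fold), Dhrs2 (90-fold), the ubiquitin-conjugating enzyme gene Ube2c (80.8-fold), the spindle gene Haus5 (80.4-fold), Cdca3 (74.1-fold) and Ddx43 (71.4-fold). The largest falls after Avp, Folr1, Oxt and Slc17a6 were those of the hormone gene Trh (61.7-fold), Kl (42.8-fold), Clic6 (42.2-fold), Calml4 (41.4-fold), the prohormone convertase gene Pcsk1 (37.4-fold) and Gpr101 (37.3-fold). Among genes not well above background in normal brain, Prm1, which encodes the sperm protein protamine 1, was at least 5950-fold higher in glioma. With normexp its fitted change was 1290-fold, which is not a measured size, as its normal brain signal was not well above background. Prm1 was followed by the stomach proton pump gene Atp4a (at least 142-fold), the spindle gene Aspm (89.8-fold), Hoxa3 (at least 83.5-fold) and Ect2 (78.2-fold). For Aspm and Ect2 the normal brain values lay above the floor used for the bounds. Their values are therefore the fitted folds and not conservative bounds. Among genes not well above background in glioma, the neurotrophin gene Ntf3 was at least 38.5-fold lower, Prr32 at least 32.4-fold, Cldn2 at least 31.3-fold, Cbln4 at least 23.6-fold and Fgf10 at least 23.1-fold.

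Haus5 and Atp4a lie in a stretch of neighbouring chromosome 7 genes in which runs of genes were higher in each glioma. It was chosen after the values were seen. The stretch was found with a running median over 9 genes in chromosome order, taken for each glioma over the normal brain mean. The running median exceeded 2 log2 units from Arhgap33 to Scgb2b2 in glioma 1, from Cox7a1 to Gapdhs in glioma 2 and from Zfp382 to Gapdhs in glioma 3, with short breaks, and reached 5.92, 5.92 and 4.57. Of the 61 tested genes from Zfp382 to Scgb2b2, 46 were at least 2 log2 units above normal brain in at least 1 glioma and 22 in every glioma. The gliomas differed in parts of it. The calpain subunit gene Capns1 lay 0.60 above normal brain in glioma 1, against 3.80 and 4.34 in gliomas 2 and 3, and Cox6b1 lay -0.33 from it in glioma 3, against 4.02 and 3.60 in gliomas 1 and 2. The list members Tyrobp and Mag fall in this stretch, and the log2 change of the myelin gene Mag, 0.15 ± 1.32, combined 0.07, 2.49 and -2.10 in gliomas 1 to 3.

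**Figure D3:**
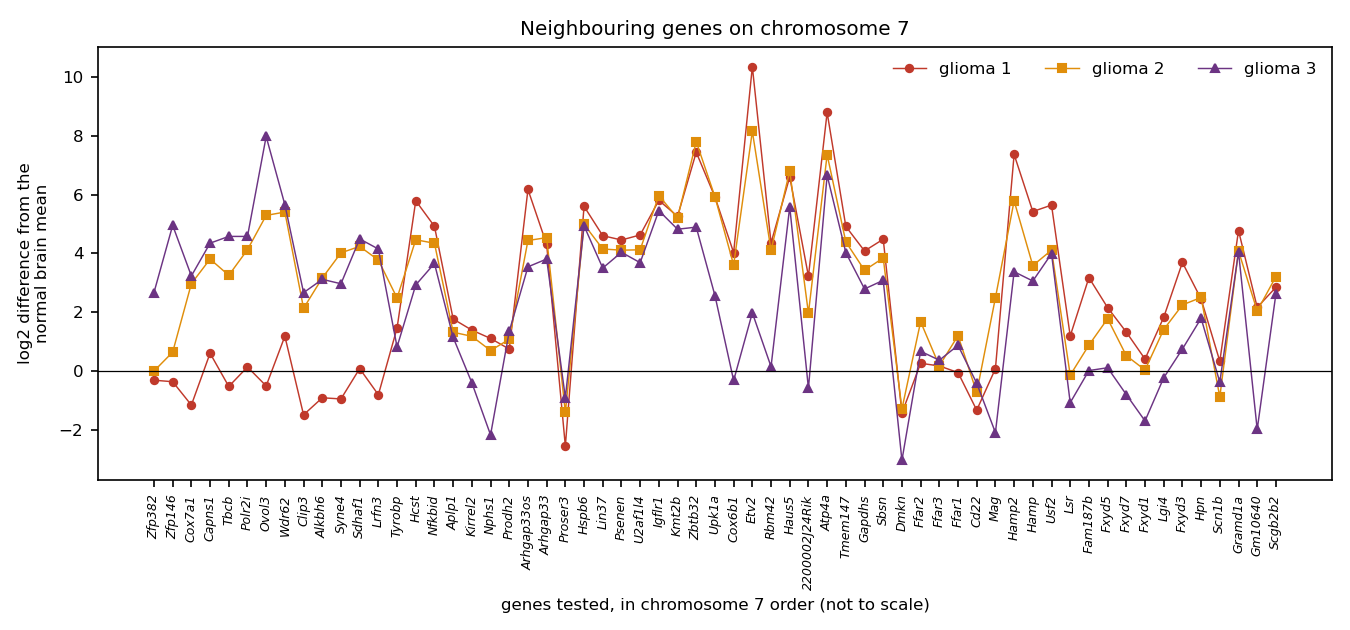
Log2 difference of each glioma from the normal brain mean (vertical axis) for the 61 tested genes of the chromosome 7 stretch, in chromosome order and not to scale (horizontal axis), with 1 line per glioma and the normal brain mean at 0. From Cox7a1 to Lrfn3 gliomas 2 and 3 lie above glioma 1, and at Cox6b1 and Rbm42 gliomas 1 and 2 lie above glioma 3.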

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

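The tests below were chosen after the results were seen, except the distance between spots, which was planned before any result but whose printed value comes from a second run, made on a longer stretch after the first result on a shorter one was seen. Probes for genomic intervals, which name no gene and were not used in the comparison, gave a signal in data outside the main measurement: of 9063 tested, 1321 were higher in glioma and 796 lower at an adjusted p under 0.05. Among intervals with at least 3 tested probes, all higher in glioma, the highest fitted median log2 changes were 6.81 on chromosome 1 (186560855 to 186563399, mm9), 5.43 on chromosome 15 (90074814 to 90087814), 5.21 on chromosome 14 (105988692 to 105994145), 5.16 on chromosome 7 (31993375 to 31999171) and 4.96 on chromosome 13 (34693404 to 34717987). Among those with all probes lower, the lowest were -5.14 on chromosome 3 (34497447 to 34501170) and -4.59 on chromosome 8 (83210957 to 83219451). The sizes are not exact where a group lies near background: in normal brain none of the 3 probes on chromosome 1 and 1 of the 5 on chromosome 15 were well above it on any array, and in gliomas 1 and 3 the mean signal on chromosome 3 lay below the lowest value well above it.

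In the chromosome 7 stretch from Zfp382 to Scgb2b2, runs of genes were higher in each glioma, starting at a different gene in each, and 22 of the 61 genes were at least 2 log2 units above normal brain in every glioma. A difference in the mix of cell types stays open. In gene order, the running median over 9 genes of the range between gliomas reached 4.47 log2 units. In 1000 shuffled orders it reached at most 3.04 (permutation p = 0.001, the smallest possible). Shuffling also separates co-regulated neighbours, so this comparison cannot decide. The real order reached 4.21 around Igf1r as well. There too a run of neighbours lay furthest above normal brain in 1 glioma, so it is no background of ordinary neighbours. The range does not bear on the genes high in every glioma. For the fitted log2 change, the running median reached 5.09 at Upk1a in the stretch, against at most 4.36 in shuffled orders. It reached 5.67 at Hoxa3 on chromosome 6, so the stretch was not the highest. A defect at 1 place of the slide is argued against, as the spots of the stretch's probes lay no closer together than those of random probe sets (median distance 139 against 136, permutation p = 0.646). A gain of copies of the stretch could raise most of its genes, and 75.4% were at least 2 log2 units above normal brain in at least 1 glioma, but the genes were chosen by such values, so a gain cannot be told apart from a change in transcription or in cell types, and DNA copy number was not analysed here.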

How the results depend on the processing

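Of the alternatives below, only the fit without the genes of the chromosome 7 stretch was chosen after the result was seen; it gave 8685 calls, with medians of -1.61 for the myelin list and 1.49 for the microglia list. Normalization, filters, probe choice, variance model and array weights kept the number of calls within 1.5 times. It was 8263 with the replicate block, in which deviations of samples sharing a number correlated at 0.0131 and 0.049, and nothing pairs these samples. Treat at 1.5-fold called 4832 genes, 2067 higher and 2765 lower, as it asks for a larger change. Leaving out 1 sample gave 4630 to 9325 calls, 1973 to 4333 higher and 2626 to 4992 lower, the fewest without a normal brain sample, where the lone sample is assumed to vary like the gliomas. Slide and scan as a block was not run, because all arrays share 1 of each. Signal over background limits the sizes given for dim genes: with normexp and its offset, 73 of 168 named genes changed by over 1.5 times less.

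With an estimated correlation none of the 24 lists passed: adjusted p was 0.239 for progenitor, neural stem, antigen presentation, cortex and striatum lists, 0.244 for choroid plexus, 0.317 for mitosis, replication, GABAergic, endothelial, mural, mesenchymal, red blood cell and diencephalon lists, 0.33 for pan-neuronal, glutamatergic, interferon, glycolysis, RAS-ERK and ependymal lists, 0.462 for oxidative phosphorylation, 0.467 for myelin and astrocytes and 0.541 for microglia. With fry the microglia list no longer passed (0.105), and hypoxia (0.003), drivers (0.00122), IGF (0.00116), immediate-early (0.0369), cerebellum (0.0108) and olfactory bulb (0.003) did. The diencephalon list stopped passing without the detection filter (median -2.56), with the mean of probes (-3.12), array weights (-3.02) and the replicate block (-3.01), and its medians were -4.64 to -2.70 when 1 sample was left out. The cholesterol list passed with array weights (-0.57), the driver list without the filter and with the mean of probes (both 0.69) and the immediate-early list in the value table (-0.57). Medians with 1 sample left out were -0.58 to -0.33 for cholesterol, 0.63 to 0.77 for drivers, -1.50 to -0.76 for immediate-early and -1.95 to -1.35 for cerebellum. The cause was not tested. Msi1 reversed to 0.108 with the mean of its probes. Of 168 named genes, 29 and 32 stopped passing without normal brain replicates 1 and 2, at most 9 without a glioma, 6 in the value table (among them Nf1, Egfr and Itgam), 4 besides Msi1 with the mean of probes, and at most 4 under any other setting. With the filter on all 5 arrays only 130 of them were tested, and none of these changed its call.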

Other observations

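All tests in this part were chosen after the results were seen. Homeobox genes of the Hoxa cluster, which pattern the hindbrain and spinal cord of the embryo, were higher in glioma in 7 of 11 cases, with 2 others not passing and 2 not tested. Hoxa7 rose by 6.83 ± 0.64 log2 units and Hoxa2 was at least 53.7-fold higher. Hoxa4 and Hoxa6, detected on 1 of the 2 normal brain arrays, rose by 3.46 ± 0.36 and 1.54 ± 0.31. Hoxa9 (-0.09 ± 0.40) and Hoxa10 (0.20 ± 2.36) did not pass. In the Hoxd cluster 3 of 9 genes were higher and 6 not tested: Hoxd4, Hoxd8 and Hoxd9 were at least 31.3-fold, 57.7-fold and 34.8-fold higher. Next to Cdkn2a, the cell cycle inhibitor gene Cdkn2b rose by 5.05 ± 0.52 and Mtap by 2.17 ± 0.22, and Dmrta1 was at least 18.7-fold higher. With normexp background correction, whose offset shrinks changes of dim probes, the log2 changes were smaller: 5.70 for Hoxa7, 3.79 for Hoxa2, 1.72 for Hoxa4, 0.65 for Hoxa6, 2.82, 3.78 and 3.34 for Hoxd4, Hoxd8 and Hoxd9, and 2.49 for Dmrta1.

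In a run of 6 neighbouring genes elsewhere on chromosome 7, every gene lay furthest above normal brain in glioma 1. The growth factor receptor gene Igf1r lay 5.29 log2 units above normal brain there, against -0.04 and 1.48 in gliomas 2 and 3, and Pgpep1l 6.06 against -0.70 and -0.36. None of the 6 was called, with adjusted p from 0.19 to 0.936. The median log2 change of all tested genes of chromosome 19 was -0.51, -0.45 and -0.36 in gliomas 1 to 3, and that of chromosome 13 was 0.28, 0.21 and 0.24.

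The Hoxa rise was weighed against 2 explanations. Tissue of hindbrain or spinal cord origin, which expresses Hoxb with Hoxa genes, stays open: the median change of Hoxb1 to Hoxb8 was -0.54, but 7 of these 8 genes were too dim to be tested and the other, Hoxb4, was called higher close to background, so this value does not decide. Of the markers of midbrain and hindbrain En2 rose by 2.92 ± 0.17 and Tph2 was at least 11.8-fold higher, with a fitted log2 change of 1.88 with normexp. As a difference from normal brain tissue, lower transcript levels of the Polycomb genes, which silence Hox clusters, are argued against. The lowest change of Ezh2, Eed and Suz12 was 0.135. Genes of cell division rose in the same comparison, and levels in dividing progenitor cells were not measured. A drop from the level of such cells therefore stays open. A change in Polycomb activity without a change in these transcripts stays open and was not tested.

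Prm1 rose from not well above background to a mean of 7.32 log2 units above the array's 75th percentile. A germ-cell programme is argued against by 16 late spermatid genes, whose median change was 0.25 (SD 0.83), or 0.46 (SD 0.98) in the 9 detected well enough to be tested. Of these only Spem1 was called higher (2.97 ± 0.28, detected on 1 of 2 normal brain arrays), and Prm2, detected on all arrays, changed by -0.03 ± 0.19. A change shared by its neighbours on chromosome 16 is argued against by the 20 nearest tested genes, with a median of 0.47 (SD 0.90). Prm2, Prm3 and Tnp2 were counted both as spermatid genes and as neighbours, so these comparisons are not independent. Prm1 sequence carried by a transgene could give this signal, since Prm1 sequence is used as a polyadenylation part in some Cre constructs, but only 1 Prm1 probe was read and the labels name no transgene, so this cannot be told apart from transcription of Prm1 itself.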
